A study of Mus musculus with 4 samples.

How the data were processed

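RNA was measured in tumour epithelial cells from chemically induced mouse skin squamous cell carcinomas. Per the labels' protocols, tumours were digested with collagenase, live single cells were gated as Epcam-positive and negative for CD45, CD31 and CD140a, and Sox2-GFP-positive and Sox2-GFP-negative cells were collected into lysis buffer. Per the labels' protocols, RNA was spiked with bacterial control transcripts, amplified and biotin-labelled with an in vitro transcription kit, and hybridised to whole-genome mouse Affymetrix arrays, 1 array per sample. The authors deposited 1 table of log2 values with 45101 probe sets and 4 columns, 1 per sample. The deposited log2 scale was read from the values, which lie between 2.73 and 14.36. The submitters' processing notes name R 2.14.0. The background correction, normalization and probe set summary are not given in the sources used here; the column medians differ slightly (5.49 to 5.61), and no scaling was undone. The table holds no detection calls, so a dim value only bounds a transcript's level, and values have no depth beyond the intensity of the array.

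Groups and replicate numbers were taken from the sample titles. The 64 Affymetrix control probe sets were left out of the tests. The platform annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160; only those with 1 symbol were named. Of these, 34754 matched the RefSeq gene table (GRCm38.p6) by gene number, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over the 4 arrays, with no filter on dim genes; genes were located on chromosomes by that same table. Differences are positive minus negative on the log2 scale.

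The main test was limma (3.58.1, in R 4.3.3) with lmFit and eBayes over the 4 arrays, group as the only term, and Benjamini-Hochberg adjusted p under 0.05. It leaves 2 residual degrees of freedom, to which eBayes added a prior of 2.92. As a description of size beside the test, genes were also counted whose positive arrays all lie at least 1 log2 unit above, or all below, the negative arrays. The 31 gene lists, with 777 entries of which 729 were measured, were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; members were also adjusted over the list alone. They cover basal, suprabasal, hyperproliferative, hair follicle and sebocyte keratinocyte genes, stem cell, cell cycle, transition, adhesion, invasion, growth factor, hypoxia, signalling, inflammatory, interferon, oxidative stress, p53, sterol and immediate early genes, and markers of Merkel, sebaceous, hair shaft, immune, Langerhans, endothelial, fibroblast, melanocyte and muscle cells. Fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, was an alternative.

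The replicate numbers are shared by both groups, and the series text states that 2 tumours of 2 mice supplied the positive and negative cells, without saying that a number marks a tumour. From that text the numbers were read as pairing the arrays by tumour, a reading that the labels do not state. The main test has no term for that pairing. As a check, the differences between replicate 1 and replicate 2 in the positive arrays and in the negative arrays correlated across genes with r = 0.16 (0.20 in the brighter genes), a weak relation over genes that are not independent replicates. By mean level, the fibroblast, endothelial and immune lists lay higher in replicate 1 than in replicate 2 of both groups. The suprabasal list did so in the positive arrays only, so the check leaves the pairing undecided. The fit with the replicate number as a block, which leaves 1 residual degree of freedom, is given beside a result where it changes a call. That fit called 13 higher and 158 lower genes.

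The rule for named genes was fixed before the data were examined. It names Sox2, the 4 sort marker genes, the 15 genes per direction with the largest change among those past the threshold and, where fewer pass, those with the largest gap between any positive and any negative array, leaving out predicted genes and clone names, plus up to 4 members with the smallest p from each list and any member past the threshold. Because none passed, all 30 places went by the gap. Some list members past the threshold only with the block are named as examples, which was decided after the values were seen.

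Alternatives fixed beforehand were the replicate block, quantile normalization, equal medians, leaving out the genes with a mean below the median, the mean of a gene's probe sets, all probe sets, a trended and a robust prior, a 2-fold minimum, an adjusted p under 0.1, leaving out each array, and camera with an estimated correlation. Added after seeing the data were scaling to the 24 poly-A spike-in probe sets, the block combined with quantile normalization, with a trended prior, without the dimmer genes, and with camera at an estimated correlation, and fry with the block. The limma step was tested on simulated data with the real gene means for 18193 genes, 200 of them changed. Without a pair effect, and without the block, it recovered 42% of genes changed by 2 log2 units, 86% of those raised by 4 and 100% of those lowered by 4, and 2% of those changed by 1, with 8 false calls; with the block it recovered 0% of those changed by 2. With a simulated pair effect (SD 0.3) recovery of a change of 2 was 4% without and 2% with the block, and that of changes of 4 was 88% to 90% in both. The noise was drawn independently for each gene from the prior of the fit without the block. These rates do not carry over to the real arrays. There Defb6, at -5.56, did not pass without the block (limma adjusted p = 0.152), while Sox15, at 1.82, passed with it (0.0438). On values simulated with independent genes camera called a list raised by 0.5 and 0 of 30 unchanged lists. Correlation between genes was left out there, so the error rate for lists of correlated genes was not tested.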

Results

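Gene expression was measured on 4 whole-genome mouse Affymetrix arrays, each hybridised with RNA from tumour epithelial cells sorted from chemically induced squamous cell carcinomas of the skin. The cells carried a fluorescent reporter for Sox2, a transcription factor best known from stem cells of the early embryo and the nervous system. Arrays came from Sox2-GFP-positive cells (n = 2) and from Sox2-GFP-negative cells of the same kind (n = 2), and the series text names 2 tumours from 2 mice as the source. Both populations had been gated for Epcam, an epithelial surface protein, and against CD45, CD31 and CD140a, which mark leukocytes, endothelium and mesenchyme. The deposited log2 values had medians of 5.49 and 5.52 in the positive arrays and of 5.61 and 5.56 in the negative arrays. The number of arrays limits the precision of every value given here, since each group holds 2.

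The first comparison asked whether the sort showed in the transcripts of its own markers. Sox2 could not be read from these arrays: its only probe set lay near the floor in all 4, with log2 values of 3.50 and 3.27 in the positive arrays and of 3.14 and 3.43 in the negative arrays, beside array 5th percentiles of 3.34 to 3.37. The log2 difference was 0.10 ± 0.21 (SE, n = 2 per group, limma adjusted p = 0.842), so Sox2 transcript neither supported nor contradicted the group labels. Epcam was bright throughout, at 11.27 ± 0.74 (SD, n = 2) in positive and 11.52 ± 0.40 (SD, n = 2) in negative cells. Pecam1, which encodes CD31, read 8.44 in negative replicate 1 against 5.57 to 6.41 in the other arrays, and Pdgfra, which encodes CD140a, read 7.83 there against 4.85 to 5.96. For Ptprc, which encodes CD45, the 2 probe sets disagreed: the brighter read 4.97 in negative replicate 1 and 4.98 in positive replicate 1, while the other read 6.40 in negative replicate 1 and 3.68 to 4.30 in the others. None of these markers passed the limma test (adjusted p = 0.403 to 0.929).

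The main comparison asked which genes differ between Sox2-GFP-positive and Sox2-GFP-negative tumour epithelial cells. The widest separations were in genes that lay below the negative cells. Defb6, an antimicrobial beta-defensin of epithelia, read 5.42 and 4.48 in the positive arrays and 10.66 and 10.35 in the negative arrays, a ratio of 47.1 in favour of negative cells (log2 difference -5.56 ± 0.36 SE, n = 2 per group). Krt79, a keratin of the upper hair follicle and sebaceous duct, was 29.1-fold lower (-4.86 ± 0.54), and Klk7, a kallikrein protease of the cornified layer, 18.9-fold lower (-4.24 ± 0.34). Scel, a cornified envelope precursor, and Lgr5, a receptor of hair follicle stem cells, were 17.9-fold and 15.6-fold lower, with positive arrays at 3.63 to 4.33. The widest separation above the negative cells was in Hmga2, a chromatin protein of embryonic and tumour cells, which read 10.07 and 11.70 in positive against 8.01 and 7.98 in negative arrays, 7.43-fold higher (2.89 ± 0.55). Next came Csf3, the granulocyte colony-stimulating factor, at 6.09-fold (2.61 ± 0.45).

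No gene of the 18193 tested passed an adjusted p of 0.05 in limma without a term for the replicate number, and the lowest adjusted p was 0.152. At an unadjusted p under 0.05 stood 1773 higher and 949 lower genes. With the replicate number as a block, 13 genes were higher and 158 lower in positive cells at the same threshold (lowest adjusted p = 0.0262), while the block combined with quantile normalization, or without the dimmer genes, called 0. Of the genes called with the block alone, 10 of the 13 and 95 of the 158 also had their groups separated by at least 1 log2 unit. Counted without a test, 121 genes had both positive arrays at least 1 log2 unit above both negative arrays, and 248 had both at least 1 below. That split was 78 and 299 after quantile normalization, and 2726 and 63 after scaling to the poly-A spike-in transcripts, which raised every log2 difference by 0.79 and the median over all genes from 0.14 to 0.93. The other 2 ways of grouping the 4 arrays into pairs gave 41 and 24 genes separated by 1 log2 unit, beside 369 for the real one, and 3 groupings are too few for a share under 0.05. Groups that did not overlap by any margin were found in 6451 genes higher and 2549 lower, 49.5% of all genes, where chance ordering of 4 arrays gives 33.3%. The 2 same-number differences correlated across genes with r = 0.48, over genes that are not independent replicates.

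The 15 genes most above and the 15 most below were those with the widest gap between the nearest arrays of the 2 groups, and are given as values. Above the negative cells, folds ran from 3.12 to 7.43. After Hmga2 and Csf3 came Grip1, a synaptic scaffold protein (4.34-fold), Padi3 and Padi4, which convert protein arginines to citrulline (4.20-fold and 6.14-fold), and Wfdc2, a secreted protease inhibitor-like protein (4.62-fold). Nceh1, a cholesterol ester hydrolase, was 5.95-fold higher, and Sox15, a relative of Sox2, read 9.06 and 8.98 in positive against 7.37 and 7.04 in negative arrays. The others were Galnt6, Dcxr, Steap1, Prkg2, Faap24, Sh2b2 and Abcb1b, the last a drug efflux pump (3.15-fold). Below the negative cells, folds ran from 9.39 to 47.1 and also took in Sdr16c6, Npnt, Aadac, Clca3a1, Akr1c18, Far2, Lhx2, Cst6, Lcn2 and Ptx3. Far2 makes the fatty alcohols of sebum waxes, Lhx2 is a homeobox factor of hair follicle stem cells, Cst6 inhibits proteases in the cornified layer, and Lcn2 is an iron-siderophore-binding antimicrobial protein. Adjusted p in limma ran from 0.152 to 0.208 over these 30 genes. With the replicate block, 8 of the 15 above (adjusted p = 0.0373 for Sh2b2 to 0.0487 for Csf3) and 15 of the 15 below (0.0262 for Defb6 to 0.0475 for Lcn2) passed, and Hmga2 did not (0.0559). Where positive arrays read near 4 or less, as for Scel, Lgr5 and Sdr16c6, they lay below or near the lower quartile of their array (4.19 to 4.25), and no detection calls were used, so these folds only bound the difference.

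**Figure D1:**
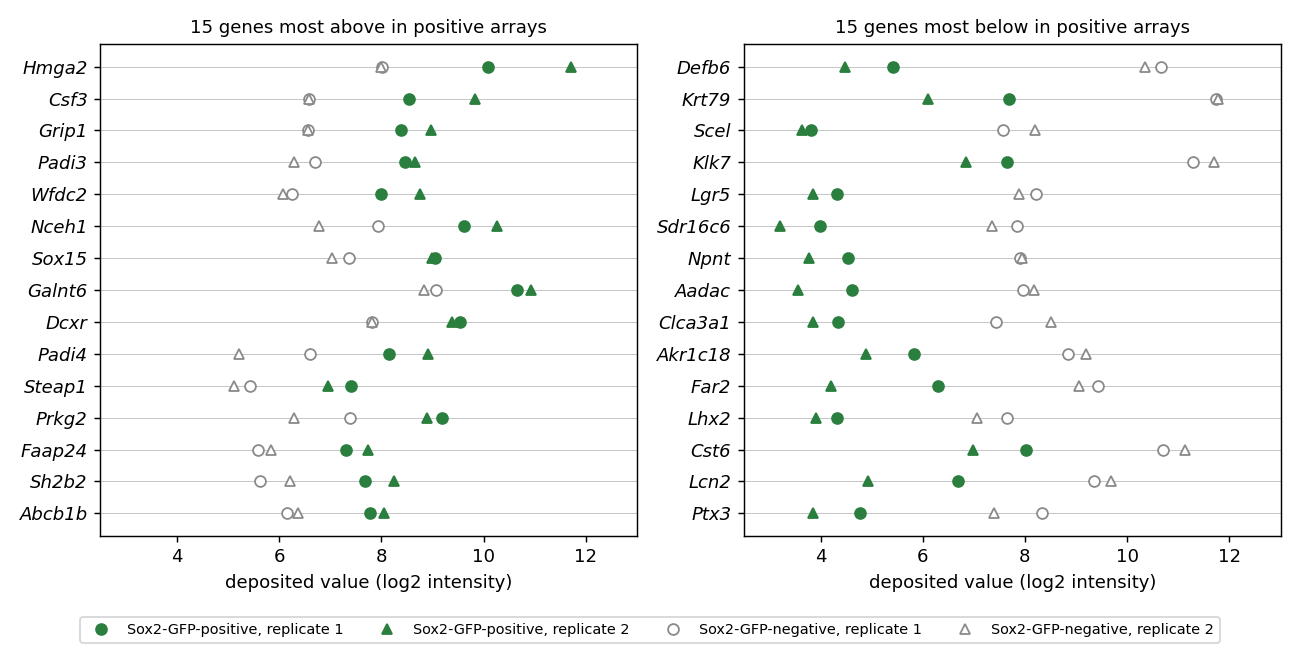
Deposited log2 values (x axis) in each of the 4 arrays for the 15 genes with the widest gap above (left) and the 15 with the widest gap below (right) the negative arrays; filled green symbols are Sox2-GFP-positive, open grey symbols Sox2-GFP-negative, circles replicate 1 and triangles replicate 2. Defb6 sits at 4.48 and 5.42 in the positive arrays and at 10.35 and 10.66 in the negative arrays, and Hmga2 at 10.07 and 11.70 against 7.98 and 8.01.

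Lists of genes fixed before the data were examined were compared with all other genes by camera. It compares the test statistics of the genes, so that a call is relative to the rest of the array. Of 31 lists, 20 were called, 15 lower and 5 higher in positive cells, with a preset correlation of 0.01 between genes. No list was called with an estimated correlation, where adjusted p ran from 0.458 to 0.599 among the 20, nor by fry, where the lowest adjusted p was 0.132. The version with an estimated correlation rests on the residual degrees of freedom, here 2, so it could hardly call a list at this threshold. Its p therefore neither supports nor undoes any 1 call, and the calls depend on the preset correlation. No list member passed over all genes without the block, while 89 passed adjusted over the list alone. Counts of list genes separated above and below stand beside 6451 above and 2549 below among all 18193 genes. Equal counts in a list are therefore fewer above, for those below, than over all genes. All 15 lower lists had medians below 0 as deposited and, relative to the median of all genes, under quantile, equal-median and spike-in scaling too. Spike-in scaling adds the same 0.79 to each, which by construction puts all of those medians above 0 except the fibroblast (-1.50) and endothelial (-0.12) ones, so directions are given relative to other genes and the absolute direction is left open.

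Genes of terminal epidermal differentiation were lower in positive cells. The suprabasal and cornified envelope list (40 genes) had a median log2 difference of -0.69 (mean -1.07 ± 1.11 SD over genes; adjusted p = 1.45e-14 by camera, adjusted p = 0.477 with an estimated correlation). The list median was -0.18 between the replicate 1 arrays and -1.25 between the replicate 2 arrays. Of the 40, 23 had both positive arrays below both negative arrays and 3 had them above. Adjusted over the list alone, 11 were lower, against 0 over all genes; with the replicate block, Klk7, Calml3 and Flg passed over all genes (adjusted p = 0.0262, 0.0420 and 0.0390). Calml3, a calmodulin-like protein of differentiating keratinocytes, read 6.61 and 6.38 against 8.53 and 8.23. Flg, which encodes profilaggrin, read 3.17 and 3.02 against 5.23 and 5.91, and the epidermal protease gene Klk5 read 4.92 and 3.97 against 6.67 and 6.90.

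Genes of hair follicle stem cells and the outer root sheath and of sebocytes were also lower, while those of the hair shaft and inner root sheath were not called (median 0.13, adjusted p = 0.664, 6 genes separated above, Padi3 among them, and 2 below). The hair follicle stem cell and outer root sheath list (22 genes) had a median of -0.49 (camera adjusted p = 1.48e-06, adjusted p = 0.458 with an estimated correlation), with 11 genes separated below and 2 above. Adjusted over the list alone, 5 were lower and 1 higher, against 0 over all genes; with the block Lgr5, Lhx2 and Nfatc1, a regulator of stem cell quiescence in the follicle, passed over all genes (adjusted p = 0.0262, 0.0262 and 0.0438). The sebocyte list (16 genes) had a median of -0.48 (camera adjusted p = 1.28e-06, adjusted p = 0.477 with an estimated correlation), with 8 genes separated below, 1 above and 7 overlapping. Adjusted over the list alone, 5 were lower, and Krt79, Far2, Cidea and Elovl3 passed over all genes with the block (adjusted p = 0.0270, 0.0344, 0.0427 and 0.0389). Scd1, a fatty acid desaturase, read 10.20 and 9.95 against 11.52 and 11.25.

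Genes of proliferating and basal keratinocytes were higher. The cell cycle list (41 genes) had a median of 0.71 (mean 0.71 ± 0.30 SD; camera adjusted p = 5.39e-12, adjusted p = 0.472 with an estimated correlation), and 38 of the 41 genes were separated above while none was separated below. Of these, 22 were higher adjusted over the list alone, against 0 over all genes. Cdk1, the mitotic kinase, read 9.74 and 9.56 against 8.28 and 8.45, and Aurka read 8.86 and 8.41 against 7.26 and 7.27. The basal keratinocyte and hemidesmosome list (18 genes) had a median of 0.56 (camera adjusted p = 0.0023, adjusted p = 0.477 with an estimated correlation), with 14 genes separated above and 2 below; 3 were higher adjusted over the list alone, against 0 over all genes. Itga3 and Itgb4, the integrins of the basement membrane contact, read 11.46 and 11.93 against 10.41 and 10.16, and 11.90 and 12.37 against 10.95 and 10.88. Without positive replicate 2 the basal list was no longer called (adjusted p = 0.0532).

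**Figure D2:**
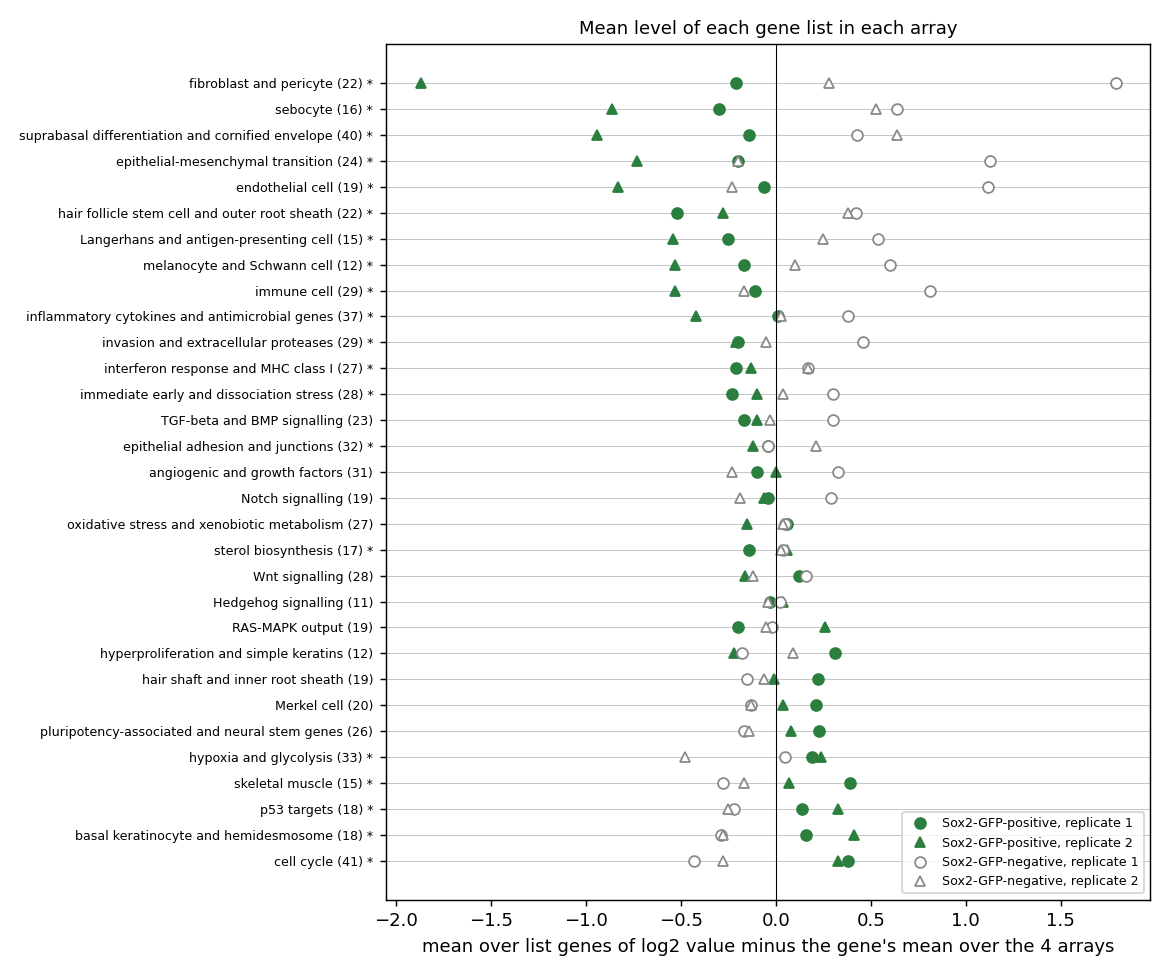
Mean over each list's genes (number of genes in brackets) of the log2 value minus that gene's mean over the 4 arrays (x axis), per array; filled green symbols are Sox2-GFP-positive, open grey symbols Sox2-GFP-negative, circles replicate 1 and triangles replicate 2, and an asterisk marks lists called by camera with the preset correlation, none of which was called with an estimated one. Cell cycle genes average 0.38 and 0.33 in positive against -0.43 and -0.28 in negative arrays, while fibroblast and pericyte genes range from -1.87 in positive replicate 2 to 1.79 in negative replicate 1; values are on the deposited scale.

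Markers of fibroblasts, endothelium and leukocytes were lower on average in positive cells, although CD140a, CD31 and CD45 had been gated out of both populations. Markers of pigment cells were lower on average too. The fibroblast and pericyte list (22 genes) had a median of -2.29 (camera adjusted p = 5.42e-11, adjusted p = 0.477 with an estimated correlation), 18 genes separated below and 1 above. Its mean level relative to the 4-array mean of each gene was -0.21 and -1.87 in the positive arrays and 1.79 and 0.28 in the negative arrays. With the block 10 of its genes passed over all genes, among them Mfap5, a microfibril protein (5.29 and 4.67 against 8.34 and 7.37, adjusted p = 0.0270), and Dpt, a dermal matrix protein (6.32 and 3.82 against 9.17 and 6.40, adjusted p = 0.0273); without it 1 passed adjusted over the list alone. Pdpn, on the same list but also made by keratinocytes, ran the other way, at 10.78 and 11.41 against 9.89 and 9.34. The endothelial list (19 genes) had a median of -0.91 (camera adjusted p = 3.48e-06, adjusted p = 0.477 with an estimated correlation). Of its genes 5 were separated below, none passed adjusted over the list alone, and with the block Emcn passed over all genes (adjusted p = 0.0390). Its mean level was -0.06 and -0.83 in the positive arrays and 1.12 and -0.23 in the negative arrays, so negative replicate 2 lay below positive replicate 1. For the immune list, given next, the levels were -0.11 and -0.53 against 0.81 and -0.17, with the same overlap. The immune list (29 genes) had a median of -0.57 (camera adjusted p = 3.39e-05, adjusted p = 0.477 with an estimated correlation), with 7 genes separated below and 2 above, none past adjusted over the list alone, and was not called without negative replicate 1 (adjusted p = 0.0568). The melanocyte and Schwann cell list (12 genes) had a median of -0.73 (camera adjusted p = 3.06e-05, adjusted p = 0.477 with an estimated correlation), with 6 genes separated below and 1 above. Tyrp1, a pigment enzyme, read 3.81 and 3.33 against 5.77 and 6.21, while Ngfr ran the other way, at 8.02 and 9.68 against 7.52 and 6.83. On that list 3 genes were lower adjusted over the list alone, and Tyrp1 and Dct passed over all genes with the block (adjusted p = 0.0421 and 0.0467). The list of Langerhans and antigen-presenting cells (15 genes) had a median of -0.20 and a mean of -0.80 (camera adjusted p = 7.84e-05, adjusted p = 0.477 with an estimated correlation). Its lower genes serve antigen presentation by MHC class II: Cd74, the invariant chain, read 8.54 and 7.60 against 11.10 and 11.24, and H2-Ab1, a class II chain, 7.80 and 7.56 against 9.94 and 9.67. Of its genes 4 were lower adjusted over the list alone, and with the block Cd74, H2-Aa and H2-Ab1 passed over all genes (adjusted p = 0.0321, 0.0282 and 0.0353).

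Genes of epithelial-mesenchymal transition were lower beside these fibroblast markers, and genes of matrix remodelling went both ways. The transition list (24 genes) had a median of -0.71 (camera adjusted p = 0.00088, adjusted p = 0.477 with an estimated correlation), and its mean level was -0.20 and -0.73 in the positive arrays and 1.13 and -0.20 in the negative arrays. Without negative replicate 1 it was not called (adjusted p = 0.247). None of its genes passed adjusted over the list alone, while with the block 7 passed over all genes, among them Cdh11, a mesenchymal cadherin (6.13 and 3.86 against 9.55 and 7.09), and Prrx1, a mesenchymal homeobox factor (6.45 and 4.76 against 9.76 and 7.57). The invasion and protease list (29 genes) had a median of -0.04 and a mean of -0.41 (camera adjusted p = 0.0422, adjusted p = 0.477 with an estimated correlation), with 11 genes separated below and 8 above; the call was lost without positive replicate 1 (adjusted p = 0.453), without negative replicate 1 (0.175) and after quantile normalization (0.107). Adjusted over the list alone 2 were lower, and with the block 7 were lower over all genes and 1, the collagenase gene Mmp1a, was higher (4.94 and 6.26 against 3.33 and 4.35, adjusted p = 0.0487). Timp3, a metalloprotease inhibitor, read 7.56 and 6.69 against 9.66 and 9.55 (adjusted p = 0.0372 with the block). Among genes of epithelial adhesion and junctions (32 genes, median -0.08, camera adjusted p = 0.0311, adjusted p = 0.477 with an estimated correlation) 1 was lower and 1 higher adjusted over the list alone. The lower gene was Nectin4, an adhesion receptor (6.96 and 6.37 against 8.03 and 8.18), and the higher was the claudin gene Cldn8 (5.11 and 5.10 against 4.01 and 3.60). The tight junction gene Cldn1, which did not pass, read 9.02 and 6.90 against 11.03 and 11.56. Cdh1, which encodes E-cadherin and did not pass either, read 9.645 and 10.357 against 10.745 and 11.181. That call was lost with the replicate block (adjusted p = 0.0656), without positive replicate 1 (0.067) and without negative replicate 2 (0.469).

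Interferon genes were lower, while inflammatory and immediate early genes went both ways. The cytokine and antimicrobial list (37 genes) had a median of -0.39 (camera adjusted p = 0.0193, adjusted p = 0.477 with an estimated correlation) with 11 genes separated below and 10 above; the list median was 0.20 between the replicate 1 arrays and -0.13 between the replicate 2 arrays. Its mean level was 0.01 and -0.42 in the positive arrays and 0.38 and 0.03 in the negative arrays, so that negative replicate 1 was highest, as it was for immune (0.81) and fibroblast (1.79) markers. Defb6, Lcn2 and the cytokine gene Il6 (4.88 and 5.43 against 8.14 and 7.60, block adjusted p = 0.0400) lay below, and Csf3 above; adjusted over the list alone 4 were lower and 1 higher. Its call was lost without positive replicate 2 (adjusted p = 0.138), without negative replicate 1 (0.247) and after quantile normalization (0.0605). The interferon response and MHC class I list (27 genes) had a median of -0.22 (camera adjusted p = 1.76e-06, adjusted p = 0.458 with an estimated correlation), with 14 genes separated below and 1 above, and 4 lower adjusted over the list alone. Oasl2 read 5.62 and 5.41 against 7.18 and 6.75, and Irf9 6.53 and 6.83 against 7.63 and 7.88. The list of immediate early and dissociation stress genes (28 genes) had a median of -0.18 (camera adjusted p = 0.000227, adjusted p = 0.477 with an estimated correlation) and 3 lower genes adjusted over the list alone. Its median was -0.38 in replicate 1 and 0.04 in replicate 2, and its mean level was again highest in negative replicate 1 (0.30). The transcription factor gene Egr2 read 8.31 and 7.28 against 11.23 and 10.50 and passed with the block (adjusted p = 0.0262).

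Of the remaining called lists, the p53 target list (18 genes) had a median of 0.35 (camera adjusted p = 0.0272, adjusted p = 0.477 with an estimated correlation), with 6 genes higher adjusted over the list alone. Cdkn2a, a tumour suppressor on the list although it acts upstream of p53 rather than as its target, read 5.99 and 6.25 against 4.75 and 4.58. Zmat3 read 7.88 and 7.63 against 6.59 and 6.24. Hypoxia and glycolysis genes (33 genes) had a median of 0.47 (camera adjusted p = 0.00629, adjusted p = 0.599 with an estimated correlation) and none past adjusted over the list alone; the glycolytic enzyme gene Pfkl read 10.82 and 11.47 against 9.72 and 9.82. The skeletal muscle list (15 genes) had a median of 0.52 (camera adjusted p = 0.00541, adjusted p = 0.477 with an estimated correlation) and 1 gene, Tnni2, higher adjusted over the list alone (7.62 and 7.80 against 6.44 and 6.54). Sterol biosynthesis genes (17 genes) had a median of -0.22 and a mean of -0.08 (camera adjusted p = 0.0313, adjusted p = 0.477 with an estimated correlation), with none past adjusted over the list alone. Calls were lost without positive replicate 2 for p53 targets (adjusted p = 0.335) and hypoxia (0.138), without negative replicate 2 for hypoxia (0.421) and sterols (0.112), without positive replicate 1 for muscle (0.067) and sterols (0.484), and without negative replicate 1 for sterols (0.175). The sterol call was also lost with the replicate block (0.102).

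The other 11 lists were not called. Camera gave an adjusted p of 0.104 for TGF-beta and BMP signalling, 0.128 for Merkel cell markers, 0.271 for oxidative stress and xenobiotic metabolism, 0.291 for angiogenic and growth factors, 0.328 for pluripotency-associated and neural stem genes, 0.434 for hyperproliferation and simple keratins, 0.435 for Notch, 0.498 for RAS-MAPK output, 0.621 for Hedgehog, 0.638 for Wnt and 0.664 for hair shaft and inner root sheath. In 7 of these (TGF-beta, growth factors, hyperproliferation, Notch, RAS-MAPK, Hedgehog and Wnt) the median was 0.03 to 0.20 while camera's direction was down. Relative to all genes, the medians of growth factors (0.03), Hedgehog (0.06) and RAS-MAPK (0.01) were above 0 too. Some members stood apart all the same. Among stem cell genes, Prom1 read 5.14 and 5.89 against 3.88 and 4.14 beside Hmga2. Tgfb1 and Ereg, 2 secreted growth factors, read 9.19 and 9.48 against 7.43 and 8.13, and 9.55 and 9.89 against 8.43 and 7.37. The Wnt inhibitor gene Wif1 read 3.49 and 3.22 against 5.86 and 5.00 (block adjusted p = 0.0433), and the connective tissue growth factor gene Ccn2 6.62 and 4.64 against 9.99 and 7.87 (block adjusted p = 0.0262). Adjusted over the list alone, 2 genes were higher and 1 lower in the Wnt list, 2 higher and 1 lower in RAS-MAPK output, 1 higher and 1 lower in oxidative stress, 1 lower in Hedgehog, 1 lower in TGF-beta and 1 higher in hair shaft, and none in the other 5. Leaving out an array gave a call for hyperproliferation without positive replicate 1 (adjusted p = 0.0412), for TGF-beta without positive replicate 2 (0.0308) or negative replicate 2 (0.0345), for RAS-MAPK without positive replicate 2 (0.0334), and for growth factors (0.0128) and Notch (0.0312) without negative replicate 2. With spike-in scaling, camera called growth factors (0.000607), TGF-beta (0.000687) and oxidative stress (0.0289) lower. Their medians relative to all genes were the same with and without that scaling (0.03, -0.08 and -0.35). These calls therefore show no move relative to other genes.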

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

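The tests of array scaling, of the spike-in shifts and of markers of other cell types were chosen after the results they measure had been seen; the test for non-tumour epithelium was written before its result.

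The bacterial spike-in transcripts, which take no part in the comparison, drew attention because they differed between the groups. All 24 poly-A probe sets, whose RNA was added before amplification, were lower in both positive arrays, by a mean log2 difference of -0.79 (-0.63 for replicate 1 and -0.95 for replicate 2), and the 11 hybridisation probe sets below saturation differed by -0.59 (-0.66 and -0.52). With a single scale factor per array as the whole cause, both kinds of control would shift alike. In replicate 2 they differed by 0.43 (-0.43 ± 0.04, SE over probe sets), which argues against it there, while in replicate 1 they were alike (0.03 ± 0.04). The SE runs over probe sets of a few transcripts and measures no spread between arrays. For the part of the poly-A shift that the hybridisation controls did not share, seen in replicate 2 only, several causes stay open. They are an uneven amount of spike-in, a different yield of amplification, and a larger amount of messenger RNA per unit of total RNA in positive cells. None of them was tested, nor was the cause of the shift that both kinds of control shared. Until that is known, whether transcripts as a whole are more abundant in positive cells cannot be read from these arrays.

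The lower level of differentiation and pilosebaceous genes in positive cells depends on that scale in absolute terms but not in relative ones. With spike-in scaling the suprabasal list had a mean log2 difference of -0.28 ± 0.17 (SE over genes), a median of 0.10 and 18 of 40 genes below 0, but that scaling adds the same amount to every gene and its own scale is in doubt, so array scaling is neither supported nor excluded for the absolute level; the list's place relative to other genes is untouched by it. Non-tumour epithelium in the negative sort, such as hair follicle or sebaceous cells carried along with the tumour, would also lower these genes in positive cells. No chromosome (0 of 20) showed a shift in both same-number differences that would mark tumour cells diluted by normal ones; chromosome 7 came nearest, at 0.08 and 0.404, the former under the minimum of 0.1. That explanation and a less differentiated state of Sox2-expressing tumour cells cannot be told apart, because the tumours need not carry a shared gain.

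Markers of fibroblasts, endothelium and immune cells were lower on average in positive arrays although the sort excluded CD140a, CD31 and CD45. A mesenchymal state of the negative tumour cells as the whole cause would leave endothelial and immune genes unchanged. Averaged over the 2 same-number differences both were lower: the less negative of their medians relative to all genes was -0.71, with means of -1.03 ± 0.15 and -0.78 ± 0.13 (SE over genes). That met the limit set against this cause, but the SE runs over genes that vary together and measures no spread between arrays. In replicate 2 the immune median alone was within the limit, so this cause is made less likely on average and is not excluded. Cells or RNA of other types in the negative sort may contribute, but the least negative of the 6 list medians was -0.27 (immune genes in replicate 2), against a limit of -0.3 set for that reading, and the others ran from -0.72 to -2.69, so this was left undecided. The abundant collagen gene Col1a1 read 12.57 and 9.60 in positive and 13.68 and 12.76 in negative arrays, Laptm5 of leukocytes 7.35 and 6.38 against 9.50 and 7.43, and Kdr of endothelium 6.65 and 5.99 against 7.77 and 6.58, but others were not lower: Cd68 of macrophages read 7.98 and 7.46 against 7.46 and 7.28, Cd14 7.08 and 7.62 against 7.42 and 6.89, and Egfl7 of endothelium 8.22 and 6.88 against 7.17 and 6.96. A mesenchymal state, alone or beside such cells, stays open, and for the transition genes that were lower beside the fibroblast markers the source cannot be told apart here.

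Among 10092 probe sets without a single gene name, 13 had both positive arrays at least 1 log2 unit above both negative arrays and 156 at least 1 below. These signals lie outside the gene comparison and no explanation was tested.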

How the results depend on the processing

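Chosen after seeing the data were spike-in scaling, the combined settings with the block, and fry with the block. No gene passed under quantile normalization, equal medians, without the dimmer genes, with the mean of probe sets, all probe sets, a robust prior, a 2-fold minimum, an adjusted p under 0.1, the block with quantile normalization or without the dimmer genes, or without any array, where a lone array is assumed to vary like the other group. The replicate block called 13 higher and 158 lower genes, a trended prior 1 and 18, both together 654 and 782, and spike-in scaling, which adds 0.79 to every log2 difference, 12559 and 158; the cause was not tested for any of these. With the block 67 of the 170 named genes passed. That number is partly set by the naming, since some list members were named because they passed with the block. With it 2 list calls were lost (adhesion and sterols), and no other list call changed.

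Genes separated by 1 log2 unit, 121 above and 248 below, numbered 190 and 435 when same-number differences were used (the replicate block), 208 and 617 over all probe sets, and 2726 and 63 with spike-in scaling. Quantile normalization gave 78 above, with the block 493 below, and leaving out the dimmer genes 155 below, since fewer genes enter. Without 1 array, counts ran from 258 to 532 above and from 418 to 746 below, since fewer arrays must be apart.

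The 20 list calls became 0 with an estimated correlation (0 with the block too) and 0 by fry (0 with the block too); 15 to 20 of them were kept under the other settings. Among the lost calls were, under quantile normalization, invasion (adjusted p = 0.107) and inflammation (0.0605), without the dimmer genes invasion (0.052), with the mean of probe sets adhesion (0.0552) and sterols (0.0767), and, with spike-in scaling, basal genes (0.0853), hypoxia (0.226), p53 targets (0.211), adhesion (0.0583) and sterols (0.525). Spike-in scaling added calls for growth factors (0.000607), TGF-beta (0.000687) and oxidative stress (0.0289). It left the median of each list relative to all genes unchanged. Neither its added nor its lost calls therefore show a move relative to other genes. Without any 1 array 10 were kept and 10 lost at least once. No called list reversed. Of the named genes, Sox2, Epcam and Ptprc changed sign when an array was left out, Ptprc also with the mean of probe sets, and spike-in scaling turned 10 by its common shift, which says nothing about them. Sox2 passed only with spike-in scaling (0.89, adjusted p = 0.021), where it shares the shift of all genes. Other pseudocounts were not run because the values are log2 already, and 3 lists (Merkel cell, melanocyte and muscle markers) were too small without the dimmer genes. Signal near background limits the dim genes, Sox2 among them.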

Other observations

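The tests of let-7 targets, of genes escaping X inactivation and of the chromosome 7 bins were written before their results were seen; the gene families and the random sets drawn for the X-linked genes were chosen afterwards.

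Chromosome 7 genes stood higher in positive than in negative replicate 2. Among 20 chromosomes, the median of 539 well-expressed genes on chromosome 7 lay 0.404 log2 units above the rest (adjusted p = 0.000667 from 10000 permutations, whose smallest p is 1e-04), against 0.08 in replicate 1 (adjusted p = 0.018). Each p compares genes within 1 positive and 1 negative array, so it does not measure the spread between samples. All 10 bins of neighbouring genes lay above the rest, from 0.28 to 0.55, 79.2% of its genes were higher, and both quartiles moved alike (0.38 and 0.39). With the chromosome median already raised, most bins could hardly lie otherwise, so their count shows only that the shift was spread along it. A chromosome gain in more of the positive cells of that array is a candidate explanation, where 3 copies in place of 2 would give 0.58. Relative to other chromosomes the level was 0.31 in positive replicate 2 and -0.07, -0.14 and -0.08 in positive replicate 1 and negative replicates 1 and 2. Most of the shift lies in positive replicate 2, and a subclone and dilution of tumour cells by normal ones in the negative sort were not separated. Chromosomes 6 and 10 shifted less, by 0.176 and 0.141 in replicate 2, and 7 others (1, 2, 3, 11, 16, 17 and X) passed there in the other direction, from -0.058 to -0.119; in replicate 1 chromosome 5 passed as well, at 0.086. Chromosome 7 held 7 of the 121 genes separated above and 14 of the 248 below, beside 7.8% of all genes with a known chromosome.

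Xist, the RNA of the inactive X chromosome, was lower in the positive arrays by a log2 difference of -0.87 in replicate 1 and -0.64 in replicate 2 at its brightest probe set, without passing the limma test (adjusted p = 0.236). Its 3 probe sets differed by -0.76, -1.03 and -0.54, with adjusted p of 0.261, 0.298 and 0.426 over all probe sets. Loss of the inactive X in some positive cells might lower genes that escape inactivation; 8 of these lay -0.22 and -0.24 from 182 other X-linked genes, the smaller of these being -0.22, past the limit of 0.2 log2 units below that was set beforehand. Random sets of X-linked genes reached both values in 5.8% of 10000 draws, a check added afterwards, so the limit alone did not set these genes apart from chance and the explanation is left open. Hmga2 is repressed by let-7 microRNAs, and 18 other let-7 targets were tested in case all had been released. Their median was 0.08, below that of all genes (0.14) as the bound set beforehand against a shared release required, but by less than the SE over genes (0.10), with a mean of 0.16, 4 genes separated above and 3 below, and a camera p of 0.99. No shared release was seen, and a modest one is not excluded.

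Families of genes sharing a name stem were compared by camera, 295 with at least 8 genes. Past the threshold were 10 higher and 2 lower with the preset correlation and 0 with an estimated one (adjusted p = 0.976). The latter could hardly call a family on 2 residual degrees of freedom. Mitochondrial ribosomal proteins had the lowest p, with a median of 0.57 over 47 Mrpl genes (adjusted p = 5.24e-06, 35 separated above and 0 below) and 0.57 over 29 Mrps genes (5.76e-05), followed by Polr, Commd, Gtf, Lsm, Psmd, Exosc, Mcm and Rad genes. Collagens (42 Col genes, median -0.47, adjusted p = 0.000502) and Adamts proteases (15 genes, -0.31, 0.00186) lay lower; with spike-in scaling these medians became 0.32 and 0.48, while relative to all genes they were below 0 under each of the 4 scalings. Fibroblast and pericyte markers, 6 of which are collagens, were lower beside them, with negative replicate 1 highest (1.79), so the collagen family is not separate from that signal. For the Adamts family this was not tested.

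The 3' minus 5' log2 signal of Gapdh, a measure of RNA integrity and amplification, was 0.35 and 0.48 in the positive arrays and 0.77 and 0.64 in the negative arrays, while that of Actb was -0.21 and -0.10 against -0.21 and -0.19. The groups thus did not overlap for Gapdh but did for Actb, and whether RNA quality contributes to the group differences was not tested.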
